A study of Homo sapiens with 3 samples.

How the data were processed

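The series measured messenger RNA levels in A498 cells, an epithelial line from a human kidney carcinoma, on Affymetrix 3' expression arrays. There were 3 arrays, 1 each for the control culture, the culture with E. coli 83972 and the culture with DRB. Per the labels' protocols, cells grown to confluence were moved to serum-free medium with gentamicin, RNA was extracted at 4 h with a column kit, and amplified RNA was labelled with biotin. The labels give 60 µM for DRB and 0.08% DMSO for the control. They state no DMSO for either treated culture, and they disagree on the bacterial concentration, so no dose is given for it. All 3 labels number the experiment as 2. Arrays of another experiment were not analysed here.

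The values used were the probe-set values the authors deposited, on a log2 scale. Per the submitters' processing notes they were made with RMA and Partek. The versions, the background step and the number of arrays normalized together are not given in the sources used here. RMA subtracts a background, brings the arrays to nearly one distribution and summarises the probes of each set on the log2 scale. A change shared by most transcripts is therefore reduced or removed by it, and differences of dim probe sets are compressed. The array medians were 4.87 for the control, 4.90 for E. coli 83972 and 4.88 for DRB. The sorted values of 2 arrays differed by at most 0.08 (E. coli 83972 and control) and 0.18 (DRB and control) on the log2 scale. No further normalization was applied in the main setting and no pseudocount was needed.

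The table held 49386 probe sets. The platform annotation listed 46586 of them, of which 45259 had 1 gene symbol and 1327 had several. A further 2800 were not listed, among them the array's own control probe sets, and these are unnamed here. Symbols were updated through the Entrez identifier with a RefSeq gene table of assembly GRCh38.p14, which gave a current symbol for 45178 probe sets. The table served for names only, so no coordinates are given. Probe sets with several genes named none.

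Each of 18239 genes was represented by its probe set with the highest mean over the 3 arrays. A gene was kept when the highest of its 3 values reached the median of all values, 4.88, which left 11653 genes. A difference is the log2 value of one array minus that of another, and a gene was counted when it was at least 2-fold in size, that is 1 on the log2 scale. With 1 array per group there is no replicate check. No test of a difference between groups was run, no p-value is given, and the number of arrays limits the precision of every value. As a measure of technical error only, the differences of the 2 brightest kept probe sets of a gene were compared over 6317 genes. The spread of that disagreement, divided by the square root of 2, gave a standard deviation of a log2 difference of 0.12 for E. coli 83972 against control, 0.15 for DRB against control and 0.17 for E. coli 83972 against DRB (robust estimates). Plain estimates, which robust ones reduce by giving discordant probe sets little weight, were 0.18, 0.32 and 0.35. In the lowest of 3 ranges of level the plain estimates were 0.23, 0.42 and 0.44. This error leaves out the variation between cultures, extractions and hybridizations. Where a gene has several kept probe sets, the mean and SD given are over those probe sets.

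Gene lists numbered 34 and were fixed, with the comparisons, the thresholds and the naming rule, before the data were examined. For each list the median difference of its kept members was set against the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list with at least 5 kept members was called higher or lower when its median lay above the 97.5th or below the 2.5th percentile of those medians. This describes these arrays and is no test across cultures. The genes named are, per comparison, the 10 with the largest increase and the 10 with the largest decrease among kept genes whose kept probe sets all differed in one direction, and up to 4 kept members with the largest differences from each list described. Genes named outside this rule are said to be so. The list of mitochondrially encoded genes had no member with a named probe set, so it gave no result.

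Both treated arrays were compared with the same control array. The overlaps of the gene sets were set beside the number for independent sets and beside 200 simulations of unchanged groups sharing 1 control, with noise taken from the disagreement of probe sets in 3 ranges of level. The calculation of differences and calls was tested on simulated data for DRB against control, with 11559 genes. It recovered 98% of true log2 changes of 1.5 in size and 100% of those of 3, and called 0 of 11360 unchanged genes. The simulated noise was equal and independent for all probe sets and small beside the 2-fold threshold. The result therefore checks the calculation and gives no rate of false calls for these arrays.

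Alternatives fixed in advance for the gene counts were other fold thresholds, no filter and a stricter filter at 6.40, the mean over probe sets, agreement of at least 2 probe sets, centring on the median of kept genes, on housekeeping genes or on all spike-in probe sets, quantile normalization again, and a loess correction by level. For the overlaps and the correlation those fixed in advance were both filters, the mean over probe sets, housekeeping genes and loess. For the lists and the 10 genes named per direction they were the same without the stricter filter. The remaining scalings and filter for these results were chosen after seeing the data. So were centring on each kind of spike-in alone and the count of genes higher with E. coli 83972 and lower with DRB. The use of only probe sets with the plain suffix _at, which leaves out suffixes such as _a_at and _s_at, was chosen then too. So was drawing the random lists again within each setting that does not shift all genes alike, to see which list calls held. Centring on 1 value shifts a list and its random lists by the same amount, so it can change the sign of a median but not a call. Scan dates and batches are not given in the sources used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.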

Results

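Messenger RNA was profiled in A498 cells, a human kidney carcinoma line that lacks functional VHL, 4 h after the addition of E. coli 83972, of DRB or of DMSO alone. E. coli 83972 is a strain that colonizes the urinary tract without causing symptoms. DRB is a nucleoside analogue that inhibits CDK9, the kinase of the elongation factor P-TEFb, and so blocks elongation by RNA polymerase II. There was 1 array for the control (0.08% DMSO), 1 for E. coli 83972 and 1 for DRB (60 µM), with no replicates, so every difference compares single arrays and not conditions. Each array gave 49386 probe-set values on a log2 scale, and 11653 genes passed the filter on low signal. Over all probe sets, Pearson's r was 0.990 between E. coli 83972 and control, 0.977 between DRB and control, and 0.968 between E. coli 83972 and DRB.

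The comparison of E. coli 83972 with control asked which host transcripts differed after 4 h with the bacterium. The labels state DMSO for the control only, so an effect of DMSO cannot be told apart from that of the bacterium. Chemokines and cytokines led the genes with higher levels. CCL20, which attracts dendritic cells and lymphocytes through CCR6, was 60.4-fold higher (log2 5.92), and CXCL8, the neutrophil chemoattractant interleukin 8, was 33.6-fold higher (5.07). IL6 was 30.3-fold higher (4.92), CXCL2 24.9-fold (4.64), CCL2, which recruits monocytes, 23.4-fold (4.55) and CXCL3 17.5-fold (4.13). PTX3, a soluble pattern recognition protein, was 16.6-fold higher (4.05), TNFAIP3, the ubiquitin-editing inhibitor of NF-κB known as A20, 15.3-fold (3.94), NEDD9, a docking protein of focal adhesions, 15.2-fold (3.93) and ICAM1, which binds leukocyte integrins, 9.06-fold (3.18). In total 222 genes were at least 2-fold higher and 76 at least 2-fold lower than control, so 74.5% of these genes were higher.

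The genes with the largest decreases included inhibitors of differentiation and stress genes. ID1, a helix-loop-helix inhibitor and target of BMP signalling, was 14.8-fold lower (log2 −3.88), and its relative ID2 was 6.33-fold lower (−2.66). PPP1R3C, a glycogen-targeting subunit of protein phosphatase 1, was 10.4-fold lower (−3.38), RGS2, a regulator of G protein signalling, 7.93-fold (−2.99) and VAV3 5.31-fold (−2.41). HSPA1B, an inducible 70-kDa heat shock protein gene, differed by −2.07, TXNIP, an inhibitor of thioredoxin, by −2.05, and the decoy receptor gene TNFRSF10D by −1.88. FOXQ1 and CTTNBP2 differed by −1.81 and −1.80. With the mean over all probe sets VAV3 (−0.88) and TNFRSF10D (−0.89) were under 2-fold. PPP1R3C, ID2 and CTTNBP2 were under the filter level on the E. coli 83972 array, where values are compressed, so their folds and ranks are uncertain.

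Among the lists fixed in advance, NF-κB target and feedback genes showed the highest median. Of 19 kept members 16 were at least 2-fold higher and 0 lower, with a median log2 difference of 1.52, against −0.16 to 0.11 for the central 95% of matched random lists. Beside TNFAIP3 and ICAM1, the members with the largest differences were TRAF1 (3.17) and VCAM1 (3.02). Cytokines and chemokines had 13 of 25 members higher and 0 lower (median 1.05, random lists −0.14 to 0.10), and a median of 0.31 without the filter, which keeps genes that are high on any array. Immediate early genes had 11 of 27 higher and 0 lower (median 0.63, or 0.37 without the filter; random lists −0.15 to 0.09), led by the MAP kinase phosphatase gene DUSP1 (3.03), ATF3 (2.92), KLF6 (2.33) and MAFF (2.24). FOS and EGR1, the classic members of that list, differed by 0.05 and 0.06. They were named after their values were seen.

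Genes of the unfolded protein and ATF4 response were also above matched lists, with 6 of 20 higher, 0 lower and a median of 0.61 (random lists −0.17 to 0.08), but 0.0021 with only plain-suffix probe sets (5 members), not set apart. DDIT3, which encodes the stress factor CHOP, was higher by 2.21, ATF4 by 1.41, CEBPB by 1.38 and PPP1R15A, which directs dephosphorylation of eIF2α, by 1.33. Circadian clock genes had a median of 0.41 (random lists −0.21 to 0.18), or 0.23 without the filter. Of 11 members 1 was at least 2-fold higher, NFIL3 at 1.53, followed by BMAL1 at 0.76, TEF at 0.70 and NR1D2 at 0.69. Adhesion and extracellular matrix genes had 2 of 19 higher, CLDN1 (1.80) and LAMB3 (1.40). Their median was 0.24 (random lists −0.15 to 0.04), or 0.11 without the filter. The sign of the median, but not its place above random lists, turned with centring on hybridization spike-ins (−0.011). Kidney epithelial and renal carcinoma genes had 0 of 16 at least 2-fold different and a median of 0.10, below 0 under all 3 spike-in centrings, which shift all genes alike. It was called higher against random lists (−0.15 to 0.09), but not without the filter (0.017) or with the mean over probe sets (0.069).

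Lists with medians below matched lists were heat shock and chaperone genes, p53 target genes, replication-dependent histone genes, nuclear oxidative phosphorylation genes and splicing regulators. Of 19 heat shock and chaperone genes 3 were at least 2-fold lower and 0 higher, with a median of −0.22 (random lists −0.14 to 0.02). They were HSPA1B, HSPA1A (−1.42) and the co-chaperone gene DNAJB1 (−1.02), and the constitutive HSPA8 differed by −0.97. HSPA1A and HSPA1B are nearly identical, and their probe sets may hybridize with both. The p53 target genes went both ways, with 2 of 21 lower, SESN1 (−1.73) and TP53INP1 (−1.61), and 3 higher, among them PLK3 (1.44) and SESN2 (1.40), around a median of −0.31 (−0.18 with the mean over probe sets; random lists −0.17 to 0.09). None of the 6 histone genes, 49 oxidative phosphorylation genes or 24 splicing regulators was at least 2-fold different. Their medians were −0.41, −0.16 and −0.17. Without the filter the median of histone genes was −0.07 over 20 members, still below random lists. Oxidative phosphorylation genes lay below 0 for 46 of 49 members, with NDUFA5 at −0.50 as the lowest, and all 6 histone genes lay below 0, with H2BC12 at −0.72.

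The other lists were not set apart from matched lists. Interferon-stimulated genes had a median just below 0 (−0.0044) and a mean of 0.19, with 2 of 34 higher, IRF1 (2.71) and GBP1 (1.46). Toll-like receptor signalling genes had a median of 0.06, with 4 of 24 higher, the kinase genes IRAK2 (2.68) and RIPK2 (1.70), the receptor gene TLR1 (1.41) and the adaptor gene TICAM1 (1.09). This list was called higher with the mean over probe sets (0.13) and with only plain-suffix probe sets (0.62, 9 members). Apoptosis regulators had a median of 0.11, with 3 of 20 higher, PMAIP1 (2.04), BCL2L11 (1.35) and BIRC2 (1.30), and were called higher without the filter (0.15), with loess correction (0.17) and with only plain-suffix probe sets (0.38, 6 members). TGF-β and BMP target genes had 3 of 15 lower, ID1, ID2 and SMAD6 (−1.32), and a median of −0.10. Of 27 transcription elongation and pausing genes (median −0.05) 2 were lower, HEXIM2 (−1.39) and HEXIM1 (−1.12), which encode inhibitors of P-TEFb, while the 12 subunits of RNA polymerase II had 0 at least 2-fold different and a median of −0.17. Antimicrobial genes had PTX3 alone higher among 5 kept members, a median of −0.07 and a mean of 0.72. Medians were 0.06 for 30 mRNA decay genes, 0.00 for 42 initiation factor and Mediator genes, −0.14 for 37 cell cycle genes, −0.04 for 231 zinc finger genes, 0.04 for 13 Notch and Wnt target genes (0.35 and called higher with the mean over probe sets, 8 members), −0.03 for 23 hypoxia-inducible factor targets, −0.13 for 17 cholesterol synthesis genes and −0.02 for 13 glycolysis genes. They were −0.03 for 66 cytosolic ribosomal protein genes, 8 small nucleolar RNA host genes and 12 housekeeping genes alike. Zinc finger genes were called lower without the filter (0.0011, random lists 0.0039 to 0.0395). Markers of other cell types did not differ by 2-fold, with medians of 0.02 for 5 leukocyte, 0.03 for 5 endothelial and −0.31 for 2 fibroblast markers.

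The differences of the 10 genes named as higher were far above the technical standard deviation of 0.12 (plain estimate 0.18), which holds no variation between cultures. Of the 130 higher genes with several kept probe sets, 101 (77.7%) had another probe set at least 2-fold higher. The size differed between probe sets for IL6, with a mean of 2.99 ± 2.74 (SD over 2 probe sets), NEDD9, with 2.60 ± 1.18 (3 probe sets), and CXCL8, with 5.85 ± 0.71 (3 probe sets). CXCL8 read 13.14 on the E. coli 83972 array, close to that array's highest value (13.20), so its fold may be compressed and its rank is uncertain. The control values of CCL20 (4.53), CXCL3 (4.69) and TRAF1 (4.65) were under the filter level, so their folds depend on the background step. The split of higher and lower genes rested on the scaling: 74.5% were higher as deposited, 57.6% with centring on all spike-ins (163 higher, 120 lower), 59.8% on poly-A spike-ins (171 and 115) and 45.3% on hybridization spike-ins (141 and 170). Of the 9 hybridization probe sets, 7 are for E. coli genes and 2 for a phage gene. Their medians were 0.32 and 0.18 with E. coli 83972, and 0.21 and −0.08 with DRB. Whether RNA of the bacterium added to the former was not tested.

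The comparison of DRB with control asked which transcripts differed after 4 h with an inhibitor of transcription elongation. Lower levels prevailed. There were 1185 genes at least 2-fold lower, which is 10.2% of the genes kept, and 15 at least 2-fold higher. The largest decreases were those of ZBED5, a domesticated transposase gene, 20.6-fold lower (log2 −4.36), EXOC8, a subunit of the exocyst, 16.2-fold (−4.02), and TADA1, a subunit of the SAGA complex (−3.91). RGS2 differed by −3.88, the mitochondrial transcription factor gene MTERF1 by −3.83, and PPP1R15B, the constitutive partner of PP1 at eIF2α, by −3.83. NAPEPLD (−3.77), the mitochondrial methionyl-tRNA synthetase gene MARS2 (−3.74), the ribosome rescue gene PELO (−3.73) and the single-stranded DNA binding gene NABP1 (−3.64) followed. PELO was lower by a similar amount in both of its probe sets (mean −3.72 ± 0.01). The means over probe sets were smaller in size for EXOC8 (−3.13 ± 1.25 over 2), TADA1 (−2.89 ± 1.44 over 2), PPP1R15B (−2.55 ± 1.40 over 3) and NAPEPLD (−2.06 ± 0.88 over 6).

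The genes with higher levels on the DRB array had smaller differences. TLN1, the gene of the integrin adaptor talin, was 4.84-fold higher (2.28), but its 2 probe sets disagreed in size (mean 1.46 ± 1.16). LPP differed by 1.49, CUX1 by 1.38, the ubiquitin ligase gene HUWE1 by 1.29, the Notch target HES1 by 1.25, ZBTB20 by 1.20, BHLHE40 by 1.15, VPS13B by 1.14, TIPARP by 1.12 and TENM3 by 1.12. With centring on poly-A spike-ins TLN1 alone stayed at least 2-fold higher. With the mean over all probe sets CUX1 (0.58), HUWE1 (0.61), HES1 (0.51), VPS13B (0.35) and TENM3 (0.89) were under 2-fold.

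Several lists of regulatory genes lay below matched lists with DRB. Immediate early genes had 10 of 27 members at least 2-fold lower and 0 higher, with a median of −0.54 (−0.28 with the mean over probe sets; random lists −0.25 to 0.20). IER5 differed by −3.02, DUSP5 by −2.55, ZFP36, which promotes decay of cytokine mRNAs, by −2.09 and IER2 by −2.06. The p53 target genes had 6 of 21 lower, 0 higher and a median of −0.59 (random lists −0.24 to 0.18), with MDM2, the ubiquitin ligase of p53, at −2.36, CCNG2 at −2.18, SESN1 at −1.86 and CDKN1A, which encodes p21, at −1.22. Cell cycle genes had 10 of 37 lower, 0 higher and a median of −0.55 (random lists −0.14 to 0.14). The centromeric histone gene CENPA (−3.07), the mitotic kinase gene AURKA (−2.74), the cyclin gene CCNE2 (−2.64) and the replication licensing gene CDC6 (−1.81) had the largest differences. Zinc finger genes, 231 in number, had 67 lower, 0 higher and a median of −0.47 (−0.15 without the filter; random lists 0.04 to 0.13), with ZNF181 (−3.07), ZNF232 (−2.78), ZNF217 (−2.62) and ZNF770 (−2.44) lowest.

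Genes of the transcription and RNA decay machinery were among them. Initiation factor and Mediator genes had 11 of 42 lower and 0 higher, with a median of −0.24 (random lists −0.20 to 0.15), led by MED17 (−2.40), TAF4 (−2.39), GTF2E1 (−2.36) and MED7 (−2.11). The mRNA decay genes had 10 of 30 lower and 0 higher, with a median of −0.53 (−0.29 with the mean over probe sets; random lists −0.19 to 0.14), led by BTG1 (−2.73), ZFP36L2 (−2.70), CNOT4 (−2.23) and DCP2 (−2.04). Splicing regulators had 2 of 24 lower, RBM5 (−2.11) and CLK2 (−1.20), and a median of −0.25 (random lists −0.13 to 0.15), or −0.12 with only plain-suffix probe sets. Elongation and pausing genes had 6 of 27 lower, among them the P-TEFb regulators HEXIM1 (−2.68), MEPCE (−2.06), HEXIM2 (−1.48) and the cyclin T2 gene CCNT2 (−1.86), but their median of −0.25 lay just inside the random range (−0.26 to 0.18), and was called lower without the filter (−0.24). RNA polymerase II subunits had a median of 0.11 and a mean just below 0 (−0.0008) with 0 of 12 at least 2-fold different.

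Hypoxia-inducible factor targets had 3 of 23 lower, PFKFB3 (−2.17), KDM3A (−2.12) and HILPDA (−1.63), 1 higher, BHLHE40, and a median of −0.28 (random lists −0.11 to 0.16), which did not hold with the mean over probe sets (−0.018). TGF-β and BMP target genes had 4 of 15 lower, ID2 (−2.88), BAMBI (−2.10), SMAD6 (−1.82) and SMAD3 (−1.17), and a median of −0.27 (random lists −0.26 to 0.22), which was not set apart with the mean over probe sets (−0.20), without the filter (−0.22) or with loess correction (−0.28), and was 0.014 for the 2 members with plain-suffix probe sets. Lists called higher against random lists were adhesion and extracellular matrix genes, with a median of 0.30 (19 members; −0.35 with centring on poly-A spike-ins), replication-dependent histone genes, with 0.38 (6 members; −0.27), and nuclear oxidative phosphorylation genes, with 0.14 (49 members; −0.51). The centring shifts all genes alike, so it changes the sign against control and not the place above random lists. Without the filter histone genes were not set apart (0.15, 20 members). None of the kept members was at least 2-fold different.

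NF-κB target genes had 4 of 19 members lower with DRB, REL (−1.60), NFKBIE (−1.54), TNFAIP3 (−1.26) and PTGS2 (−1.11), and cytokines and chemokines 4 of 25, CCL2 (−1.85), CXCL2 (−1.37), IL6 (−1.34) and TNFSF10 (−1.05). Their medians of −0.20 and −0.08 were not set apart. The unfolded protein and ATF4 response list had 6 of 20 lower, with DNAJB9 (−3.26), CEBPB (−2.72), HERPUD1 (−1.92) and XBP1 (−1.36) lowest, and a median of −0.12. Apoptosis regulators had 3 of 20 lower, the survival gene MCL1 (8.01-fold), FADD (−2.50) and XIAP (−1.10), and a median of −0.27 (random lists −0.32 to 0.20), and were called lower without the filter (−0.21) and with only plain-suffix probe sets (−0.96, 6 members). Heat shock genes had 2 of 19 lower, DNAJB4 (−2.48) and DNAJB1 (−2.43), and a median of −0.03, and were called lower without the filter (−0.06). Interferon-stimulated genes had 3 of 34 lower, IFIT3 (−1.53), IFIT5 (−1.33) and IFIT1 (−1.17), and a median of −0.06. Toll-like receptor signalling genes had 2 of 24 lower, IRAK2 (−1.57) and TBK1 (−1.10), and a median of −0.15, or −0.67 and called lower with only plain-suffix probe sets (9 members). Notch and Wnt targets had SOX4 (−1.89) and SOX9 (−1.61) lower and HES1 higher among 13, with a median of −0.37. Cholesterol synthesis genes had HMGCS1 (−1.89) and INSIG1 (−1.17) lower among 17, with a median of 0.00 and a mean of −0.21. Small nucleolar RNA host genes had SNHG12 (−1.33) and SNHG7 (−1.06) lower among 8, with a median of −0.04.

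No member of several other lists was at least 2-fold different with DRB. Medians were −0.17 for circadian clock genes, 0.16 for kidney genes, 0.08 for glycolysis genes and 0.05 for cytosolic ribosomal protein genes. Among housekeeping genes (median 0.03, mean −0.04) TBP alone was lower (−1.32), and among antimicrobial genes (median 0.30, mean −0.10) PTX3 alone (−1.66). Medians of 0.32 for leukocyte, 0.06 for endothelial and 0.33 for fibroblast markers came with 0 members at least 2-fold different. The gap between 3' and 5' probe sets, which widens with RNA degradation, was 1.98, 2.00 and 1.83 for beta-actin and 0.08, 0.16 and 0.09 for GAPDH on the control, E. coli 83972 and DRB arrays. Probe sets of poly-A RNA spiked into the samples were higher on the DRB array by a median of 0.65, with 24 of 24 above 0. They cover parts of the dap, lys, phe and thr RNAs in 1 sample and are not independent measurements.

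Of the 666 lower genes with several kept probe sets, 540 (81.1%) had all of them in one direction and 385 (57.8%) had another probe set at least 2-fold lower. The count of lower genes was 2880 with centring on poly-A spike-ins, 698 with the mean over probe sets and 1046 after quantile normalization again. On the DRB array EXOC8, TADA1, RGS2, MTERF1, PPP1R15B, NAPEPLD, MARS2 and NABP1 were under the filter level, so their folds depend on the background step.

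**Figure D1:**
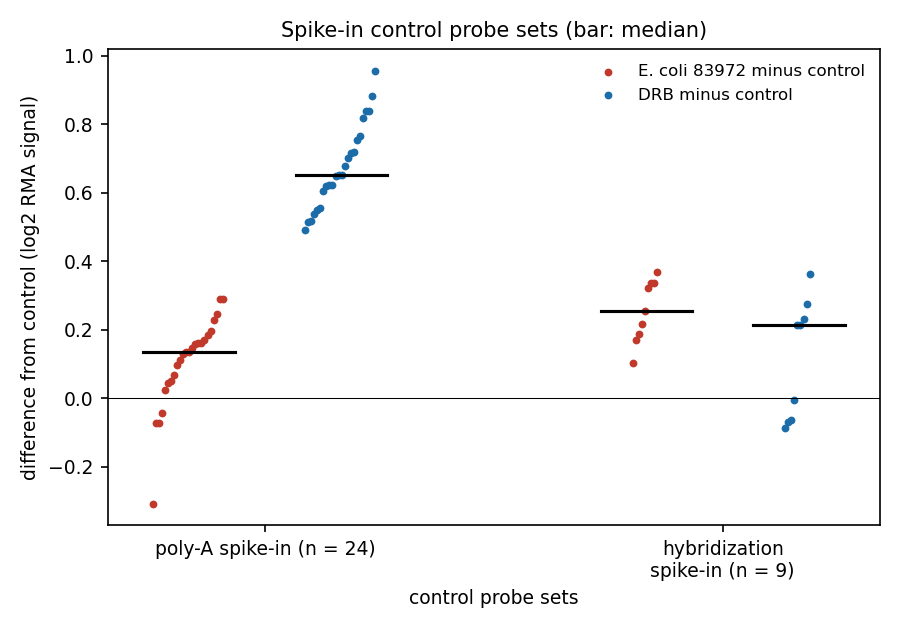
Log2 difference from the control array of each spike-in control probe set, for E. coli 83972 (red) and DRB (blue), with bars at the medians. The 24 poly-A probe sets have medians of 0.14 and 0.65 and the 9 hybridization probe sets medians of 0.25 and 0.21.

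**Figure D2:**
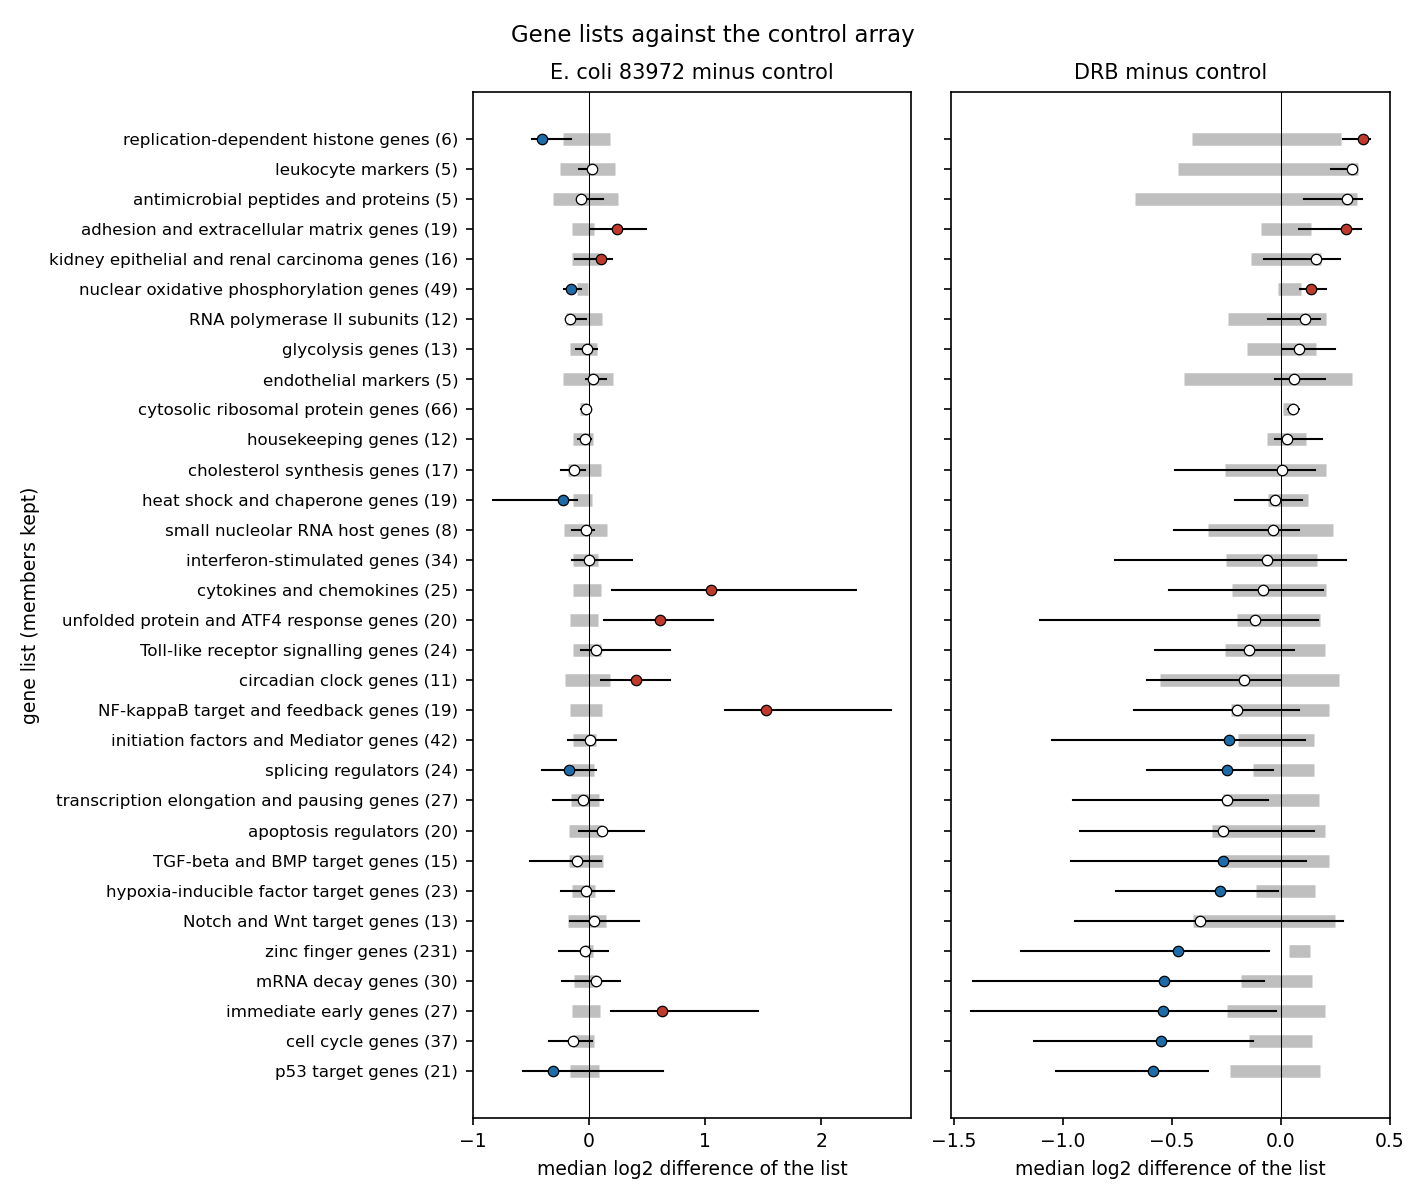
Median log2 difference from the control array of each gene list, for E. coli 83972 (left) and DRB (right). Points are medians, lines span the quartiles of the members, grey bars hold the central 95% of matched random lists, red and blue mark lists above and below that range, and numbers in brackets are kept members; the lists of 2 fibroblast markers and of mitochondrial genes are not drawn. NF-κB targets have the highest median with E. coli 83972 (1.52) and p53 targets the lowest with DRB (−0.59).

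The third comparison set E. coli 83972 directly against DRB, to relate the response to the bacterium with that to a compound that blocks RNA polymerase II. There were 1432 genes at least 2-fold higher with E. coli 83972 and 45 lower. For each gene this difference equals that from control with E. coli 83972 minus that with DRB, so it holds no new measurement. The largest differences were again mostly those of inflammatory genes. CCL2 was 84.4-fold higher (log2 6.40), IL6 76.9-fold (6.27), CXCL2 64.5-fold (6.01) and PTX3 52.5-fold (5.71). CCL20 was 50.8-fold higher (5.67), CXCL8 48.0-fold (5.59) and TNFAIP3 36.6-fold (5.19). The focal adhesion gene NEDD9 was 51.2-fold higher (5.68). PPP1R15B (5.99) and the nuclear receptor coactivator gene PNRC1 (5.58) joined them because each was higher than control with E. coli 83972 (4.47-fold and 5.46-fold) and lower with DRB (−3.83 and −3.13). These sizes and their order are uncertain, since NEDD9, CCL20 and PPP1R15B were under the filter level on the DRB array and CXCL8 was close to the highest value on the E. coli 83972 array. Means over probe sets were 3.59 ± 3.79 for IL6, 3.28 ± 2.09 for NEDD9, 4.06 ± 2.06 for PPP1R15B and 4.29 ± 1.81 for PNRC1.

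Genes lower with E. coli 83972 than with DRB were ID1 (−3.40), HES1 (−2.56), TNFRSF10D (−2.30), HSPA1B (−1.88), the arrestin domain gene ARRDC3 (−1.71), GCSH, a protein of the glycine cleavage system (−1.63), C12orf76 (−1.60), RAB4A, a GTPase of endosome recycling (−1.38), DNER (−1.37) and HSPA1A (−1.33). RAB4A, DNER and HSPA1A were under 2-fold with centring on poly-A spike-ins, and HES1, RAB4A and DNER with the mean over probe sets. HES1 and C12orf76 were under the filter level on the E. coli 83972 array. Of the lists, 13 were called higher and 2 lower. A list called higher here need not be above control with the bacterium, since lower levels with DRB give the same sign. NF-κB targets had 14 of 19 higher (median 2.05), immediate early genes 17 of 27 (1.45), cytokines and chemokines 14 of 25 (1.16, or 0.38 without the filter), circadian clock genes 4 of 11 (0.93, but 0.18 without the filter, inside the random range), mRNA decay genes 12 of 30 (0.69, or 0.44 with the mean over probe sets), zinc finger genes 62 of 231 (0.44, or 0.14 without the filter), initiation factor and Mediator genes 12 of 42 (0.30, but 0.19 with only plain-suffix probe sets, inside the random range), elongation genes 6 of 27 (0.28, but 0.12 with the mean over probe sets, inside the random range) and cell cycle genes 8 of 37 (0.25). The p53 targets had 8 of 21 higher and 2 lower (0.39). Unfolded protein and ATF4 response genes (0.68), hypoxia-inducible factor targets (0.14) and splicing regulators (0.13) were called higher, but had medians of −0.11, −0.0007 and −0.14 with only plain-suffix probe sets. The hypoxia-inducible factor targets (0.046) and splicing regulators (0.10) were not set apart with the mean over probe sets either. Histone genes (−0.85, but −0.20 without the filter; 0 of 6 at least 2-fold different) were lower, and so were oxidative phosphorylation genes (−0.28, 0 of 49), whose median was 0.24 with centring on poly-A spike-ins, a change of sign that leaves its place below random lists as it was. Among the list members with large differences were CCNG2 (2.46), KDM3A (2.57), DUSP5 (4.14), MCL1 (3.14), CENPA (3.10) and BTG1 (3.20). Medians of the other 17 lists tested lay inside the random range in the main setting. Some were far from it with only plain-suffix probe sets, as those of Toll-like receptor signalling genes (1.34 instead of 0.21) and apoptosis regulators (1.42 instead of 0.33), both called higher, and that of interferon-stimulated genes was 0.62 and not set apart. Apoptosis regulators were also called higher under alternatives fixed in advance, without the filter (0.33) and with the mean over probe sets (0.26). RNA polymerase II subunits were called lower without the filter (−0.31). Among the 17, median and mean differed in sign for interferon-stimulated genes (−0.03 and 0.37), antimicrobial genes (−0.25 and 0.82), cholesterol synthesis genes (−0.15 and 0.10), adhesion genes (−0.03 and 0.09) and housekeeping genes (−0.03 and 0.0014).

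Against the shared control, 43 genes were at least 2-fold lower on both treated arrays. They made up 56.6% of the 76 genes lower with E. coli 83972, whereas 10.2% of all kept genes were lower with DRB. SESN1 was lower by similar amounts (−1.73 with E. coli 83972 and −1.86 with DRB). For PPP1R3C (−3.38 and −3.47) and ID2 (−2.66 and −2.88) both treated arrays were under the filter level, so their sizes cannot be compared, while RGS2 (−2.99 and −3.88), VAV3 (−2.41 and −3.37) and HEXIM1 (−1.12 and −2.68) had larger differences with DRB. By contrast ID1 was lower with E. coli 83972 and differed by −0.48 with DRB. TLN1 and TIPARP were the 2 genes at least 2-fold higher on both arrays, and HES1 was the 1 gene lower with E. coli 83972 (−1.31) and higher with DRB, though under 2-fold with DRB with the mean over probe sets (0.51), poly-A centring (0.60) or plain-suffix probe sets (0.64). Independent sets would share 7.73 lower and 0.286 higher genes. Unchanged groups simulated with a shared control shared 0 of either, but their noise came from probe sets and was far under 2-fold, so this count leaves out variation of the control culture. The control was a single array, of a culture with DMSO, and could not be split, so part of the excess may come from it.

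A further 76 genes were at least 2-fold higher with E. coli 83972 and at least 2-fold lower with DRB, against 22.6 for independent sets. They were 34.2% of the 222 genes higher with the bacterium and included CCL2, IL6, CXCL2, PTX3, TNFAIP3 and PPP1R15B. The median DRB difference of the 222 genes was −0.58, with 179 below 0 (80.6%), that of the 76 genes lower with E. coli 83972 was −1.25, and that of all other kept genes was 0.06. CXCL8 differed by −0.51 with DRB. CCL20 showed no decrease, with 4.53 on the control array and 4.78 on the DRB array. Both values were under the filter level, where differences are compressed. Across the 11653 genes, which are not independent replicates, the differences of both comparisons were nearly uncorrelated (Pearson's r −0.03, Spearman's rho 0.02). Simulated groups in which no gene differs gave r = 0.50 from the shared control alone, which is no yardstick for groups with real differences. The covariance was −0.0070 against a simulated 0.0091, a difference of −0.0161, or against 0.0175 with plain noise estimates, a difference of −0.0245. The simulated noise came from E. coli 83972 against control alone and held no variation between cultures. The difference is therefore no correction for the shared control.

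**Figure D3:**
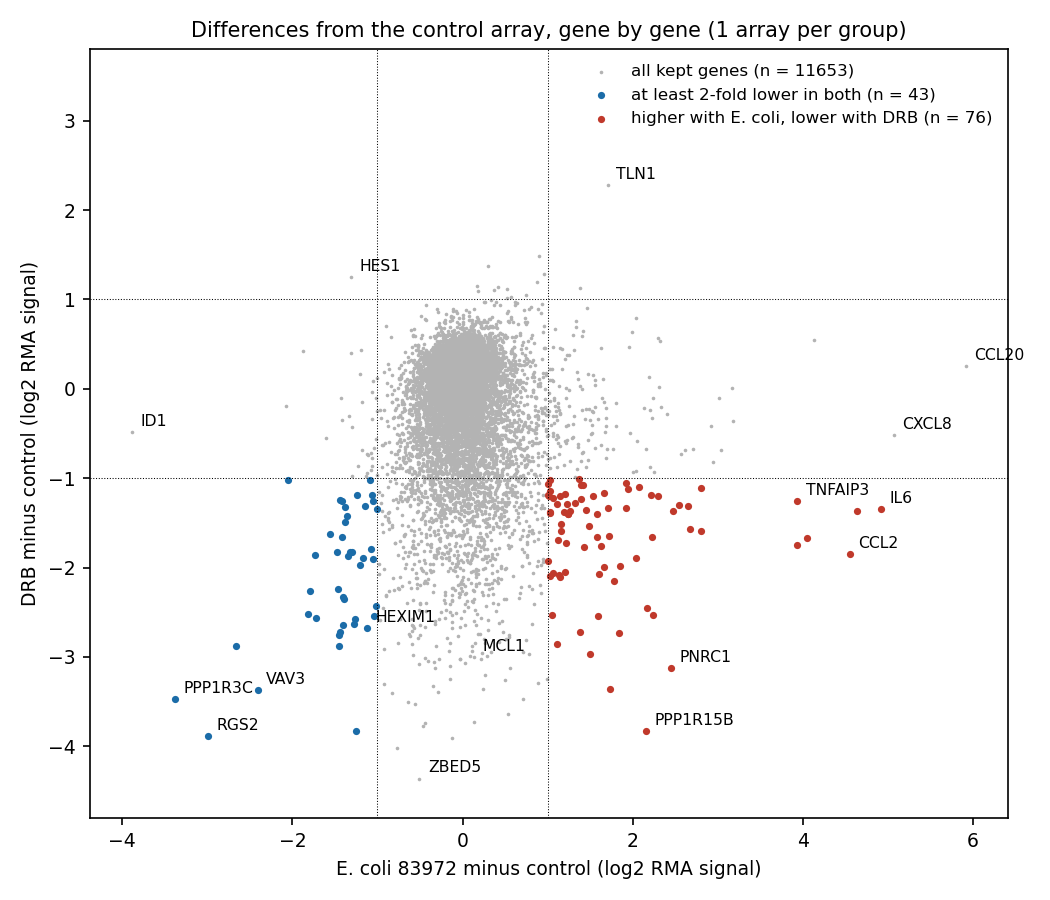
Log2 difference from the control array with E. coli 83972 (horizontal) and with DRB (vertical) for each of 11653 kept genes. Blue points are the 43 genes at least 2-fold lower in both, red points the 76 genes higher with E. coli 83972 and lower with DRB, and dotted lines mark 2-fold.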

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

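Of the tests in this part, those of RNA degradation and of spike-ins, and the use of the scalings to weigh the normalization, were chosen after the results were seen, while most of the scalings themselves were fixed before. The signals described are those of control probe sets and of probe sets without a gene name, and the excess of lower genes on the DRB array is weighed beside them.

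The poly-A spike-in probe sets, for bacterial RNA added to each sample before amplification, were higher on the DRB array than on the control array by a median of 0.65 on the log2 scale (mean 0.68, SD 0.13 over 24 probe sets), which is 1.57-fold. These probe sets cover parts of the dap, lys, phe and thr RNAs in 1 sample. Their SD is therefore no measure of variation between samples. The spike-ins added at hybridization were higher by 0.21, a gap of 0.44 that exceeds their SD of 0.17 over probe sets. This gap cannot decide on a brighter hybridization of the whole array, because RMA had already brought the arrays to nearly one distribution. The SD of 0.17 comes from 1 hybridization per array too. A candidate explanation is that the DRB sample held less poly-A RNA per amount of total RNA, which would also raise the poly-A spike-ins, by an amount that was not predicted. An unequal amount of spike-in or of total RNA would do the same, and as these amounts are not given in the sources used here the explanations cannot be told apart.

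The preponderance of lower over higher genes on the DRB array was weighed too. Further scaling did not remove it, since 1046 genes were at least 2-fold lower under the scaling that gave the fewest. Each scaling started from the deposited values and cannot undo the authors' normalization, so that normalization as a cause could not be tested. Degraded RNA is argued against, since the 3' to 5' gap on the DRB array was wider than on the control by 0.01 for GAPDH (0.0096) and narrower for beta-actin. A biological effect of DRB stays open as a hypothesis, because a single culture was measured and a difference between cultures was not tested.

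The 5' probe set of 28S ribosomal RNA was higher than on the control array by 0.58 with E. coli 83972 and by 0.56 with DRB, but the median of all 3 of its probe sets was 0.08 and 0.21, and the lowest differed by −0.07 and 0.14. Among the 2713 probe sets without a gene name, 14 were at least 2-fold higher and 15 lower with E. coli 83972, and 5 were higher and 101 lower with DRB.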

How the results depend on the processing

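The scalings by 1 kind of spike-in, the use of plain-suffix probe sets alone, and every scaling of an overlap, the correlation, a list or a named gene other than housekeeping and loess centring were chosen after the results were seen. No replicate could be left out, since each group had 1 array. No paired analysis was possible because each group had 1 array and no result comes from a test. Signal over background limits the folds of dim genes, whose values RMA compresses. Of the alternative values of counts, overlaps and the correlation, 70 stayed close to the main value and 58 moved. Of list medians 685 stayed, 348 moved and 17 reversed. For the 10 genes named per direction in each comparison, 419 values stayed, 162 moved and 40 dropped under 2-fold. Genes named only as list members were not followed under the alternatives. The correlation stayed between −0.08 and 0.01. Unless said otherwise the cause of a difference was not tested. Counts are given as higher and lower genes, for E. coli 83972 against control, DRB against control, and E. coli 83972 against DRB; the main counts are 222 and 76, 15 and 1185, and 1432 and 45.

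A lower threshold counts more genes by construction. At 1.5-fold they were 605 and 357, 237 and 2106, and 2254 and 667, and at 3-fold 83 and 13, 1 and 503, and 682 and 7. Fewer genes were open to counting where at least 2 probe sets had to pass, with 113 and 25, 8 and 432, and 611 and 16, and with plain-suffix probe sets alone (3459 genes), with 82 and 22, 7 and 401, and 497 and 17. With the mean over probe sets there were 43 lower with E. coli 83972, 6 higher and 698 lower with DRB, and 914 higher and 21 lower between the treated arrays.

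Centring on all spike-ins shifted the 3 comparisons by −0.16, −0.62 and 0.46, on poly-A spike-ins by −0.14, −0.65 and 0.52, and on hybridization spike-ins by −0.25, −0.21 and −0.11; such a shift moves genes across the threshold by construction. With all spike-ins there were 120 lower with E. coli 83972, 1 higher and 2759 lower with DRB, and 2371 higher and 7 lower between the treated arrays. With poly-A spike-ins these were 115, 1 and 2880, and 2553 and 7. With hybridization spike-ins there were 141 higher and 170 lower with E. coli 83972, 5 higher with DRB, and 91 lower between the treated arrays. Most hybridization probe sets are for E. coli genes, so this scaling may not be neutral for the culture with the bacterium. Quantile normalization again gave 30 higher with DRB and 91 lower between the treated arrays, where centring on the median gave 29.

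The 43 genes lower in both became 27 with the mean over probe sets, 93, 90 and 101 with all, poly-A and hybridization spike-ins, and 13 with plain-suffix probe sets. The 2 genes higher in both became 1 under each of these 5 settings. The 76 genes higher with E. coli 83972 and lower with DRB were 60 to 108 under the scalings, 40 with the mean over probe sets and 24 with plain-suffix probe sets.

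List medians reversed as follows, and the shift given above accounts for those under spike-in centring. With all, poly-A and hybridization spike-ins, oxidative phosphorylation genes with DRB were at −0.48, −0.51 and −0.074, and kidney genes with E. coli 83972 at −0.060, −0.035 and −0.15. With all and poly-A spike-ins, histone genes with DRB were at −0.24 and −0.27, adhesion genes with DRB at −0.32 and −0.35, and oxidative phosphorylation genes between the treated arrays at 0.17 and 0.24. Adhesion genes with E. coli 83972 were at −0.011 with hybridization spike-ins. With plain-suffix probe sets, TGF-β and BMP targets with DRB were at 0.014, and between the treated arrays hypoxia-inducible factor targets were at −0.0007, unfolded protein and ATF4 response genes at −0.11 and splicing regulators at −0.14, all with fewer members.

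Random lists were drawn again within each setting that does not shift all genes alike. Of 39 list results called higher or lower, 8 were no longer set apart under at least 1 alternative fixed in advance, and of 57 not called 11 were. The calls lost were those of hypoxia-inducible factor targets with the mean over probe sets (DRB −0.018, between the treated arrays 0.046), of elongation genes (0.12) and splicing regulators (0.10) between the treated arrays with that mean, of circadian clock genes between the treated arrays (0.18) and histone genes with DRB (0.15) without the filter, and of TGF-β and BMP targets with DRB and kidney genes with E. coli 83972 under several. With only plain-suffix probe sets 17 of the 39 were not set apart and 13 had too few members, while 9 lists not called before were. No call changed direction. Without the filter, members that are dim on all arrays count too, and medians with E. coli 83972 were 0.31 for cytokines and chemokines, 0.37 for immediate early genes and −0.069 for histone genes, and that of zinc finger genes with DRB was −0.15, all still set apart.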

Other observations

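Of the tests in this part, the match on control level was written down before its result was seen, and that of short-lived transcripts, like the weighed pattern itself, was chosen after. The genes named in this part were chosen after their values were seen.

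Several regulators outside the lists and the naming rule had large opposite differences. CEBPD, a transcription factor gene of the acute phase response, was higher with E. coli 83972 (log2 1.74) and lower with DRB (−3.36). FOXO1 (2.23 and −2.53), the cytokine signalling inhibitor gene SOCS2 (2.17 and −2.45), the amino acid transporter gene SLC38A2 (1.84 and −2.73) and TIFA, an adaptor upstream of NF-κB (2.83-fold higher and −2.97), showed the same pattern. Among genes lower on both arrays were CCNF, the gene of cyclin F (−1.45 and −2.75), BORA, an activator of Aurora A (−1.44 and −2.73), E2F8 (−1.40 and −2.64), the methionine adenosyltransferase gene MAT2A (−1.04 and −2.54) and PANK1, a kinase of coenzyme A synthesis (−1.72 and −2.56). On the DRB array CEBPD, FOXO1, SOCS2, BORA, E2F8 and PANK1 were under the filter level of 4.88, as was PANK1 with E. coli 83972, so these sizes are uncertain.

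Genes at least 2-fold higher with E. coli 83972 were at least 2-fold lower with DRB more often than other genes, 76 of 222. The control level of the genes is argued against as the whole cause, since 10000 random sets matched on it held a mean of 27.4 such genes and at most 49. A candidate explanation is that genes with short-lived transcripts are overrepresented both among those the bacterium raises or lowers and among those DRB lowers; in accord with it, 43 of the 76 genes lower with E. coli 83972 were lower with DRB, against a mean of 10.2 and at most 22 in matched sets. It stays open, because those 43 genes share 1 control culture and no decay rate was measured; the reading of this test was set to open, rather than as a fit to the explanation, after its result was seen.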
